A study of Homo sapiens with 13 samples.

How the data were processed

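Single-cell RNA was measured in 13 human tumours with 10x Genomics Chromium libraries: 1 ductal carcinoma in situ (DCIS), 5 triple-negative breast cancers (TNBC), 5 anaplastic thyroid cancers (ATC) and 2 invasive ductal carcinomas (IDC). Single-cell suspensions were made from fresh tumours collected before treatment. The labels give 3' chemistry for all libraries except those of the IDC tumours, which they give as 5', although the protocol named for those is a 3' one as well. TNBC, DCIS and IDC tumours are labelled as biopsies and ATC tumours as surgical samples, so sample type and tumour type cannot be told apart. Each tumour is 1 biological replicate, and no tumour was measured more than once.

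The values deposited by the authors are raw UMI counts per gene and cell, made with CASAVA 1.8.1 and Cell Ranger 3.0 per the labels, for cells the authors had filtered. The genome build and the filter on cells are not stated. With the counts the authors deposited 2 calls per cell of aneuploid or diploid, made with COPYKAT, which infers copy number from expression along the genome. The call named after COPYKAT set the classes here, and the second, named after clusters, was an alternative. They differed in 979 of 36201 cells (2.7%, at most 8.9% in a tumour). Because COPYKAT makes its call from the same counts, genes that differ between the classes are not independent of the call.

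The files have 33694 or 33538 gene rows. Gene names were matched through RefSeq synonyms, which joined 22677 genes (22161 by the same name, 516 by an older one) that held 99.2 to 99.5% of the UMIs of each library. Genome positions are those of GENCODE 29 on GRCh38. Libraries held 532 to 6226 cells, 14603654 to 80625625 UMIs in all, and a median of 5226 to 21522 UMIs per cell. The fewest UMIs in any cell were 5323 to 10763 in DCIS tumour 1 and TNBC tumours 1 to 3, the libraries with 33694 gene rows, and 509 to 848 in the other 9. An alternative therefore kept only cells with at least 10763 UMIs in every library. The barcodes follow 2 different lists: TNBC tumours 4 and 5 and ATC tumours 2 and 5 use the second, and the other tumours the first. The lists were treated as library batches, by a term in the model and by fits within each list. Within the first list all TNBC libraries have 33694 gene rows and all ATC libraries 33538. Comparisons of ATC with TNBC within that list therefore cannot separate tumour type from gene rows and UMI minimum.

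Cells were clustered with scanpy 1.11.5, scikit-learn 1.9.0 and leidenalg 0.10.2 on Python 3.11.15, with 2000 variable genes, 40 principal components, 20 neighbours, seed 1 and Leiden resolution 1 (0.5 and 2 as alternatives). Markers of 18 cell types, fixed beforehand, named clusters: a name needed at least 3 markers raised 2-fold and seen in at least 10% of the cells. Clusters whose leading genes belonged to another type, or that had few UMIs and no marker among the leading genes, stayed unnamed. T cell-like and NK cell-like clusters were joined to 1 class after the clusters were seen, and the rules on leading genes were also set then. The result was 48 clusters, 24 of them named in 11 classes and 24 unnamed (17866 cells, with 20 of the clusters mostly aneuploid). Doublets were called by Scrublet with an expected rate of 0.06. It called 208 cells (0.575%), and only 0.048% of ATC tumour 2, so it can have missed doublets there and removing its calls tests little.

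For comparisons of genes, UMIs were summed per tumour and class where at least 20 cells were present. The sums held 1867179 to 77699745 UMIs for the aneuploid and diploid classes and 221545 to 10039675 for macrophages or monocytes. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood with robust estimation) in R 4.3.3, at an adjusted p (Benjamini-Hochberg) under 0.05, and reported as log2 fold changes with their standard error (SE). Levels are CPM (UMIs per 1e6 UMIs of the sum) as mean ± SD over tumours. Beside a fold change they are scaled by TMM over the sums of that comparison, so a gene can have slightly different levels in different comparisons. Levels in the plots, of single tumours and beside the DCIS and IDC tumours are not scaled. The comparisons were aneuploid against diploid cells within TNBC and within ATC (tumour as block), the difference between those contrasts, ATC against TNBC aneuploid cells, and ATC against TNBC macrophage-like cells. The last of these could be run in 5 ATC and 4 TNBC tumours. Title numbers do not pair tumours: correlations between tumours of the same number were -0.0642 to 0.028 in aneuploid cells and -0.14 to 0.308 in macrophage-like cells, with 1 of 4 pairs over 0.1.

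Gene lists (23, fixed before the data were examined) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. Medians and shares per tumour were compared by exact two-sided permutation tests. Genome arms with at least 30 genes of mean CPM of 10 or more were scored per tumour, and 39 arms were tested with limma. The score was the median over an arm's genes of the log2 ratio of aneuploid to diploid CPM (pseudocount 1). The ratios were first centred on the tumour's median over all genes of that level. Splits among the aneuploid cells were sought in bins of 25 neighbouring genes: cells were split on the odd genes of each bin, and the correlation of the split's profile over the even genes was set against 100 permutations of gene order. Shares of a single tumour carry exact Clopper-Pearson 95% intervals and single counts Poisson 95% intervals, and these cover counting error only.

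Named genes were chosen by a rule written before the data were examined, as were the main tests, gene lists, markers and the alternatives not named below as later. For each comparison it took the 8 largest rises and 8 largest falls (5 and 5 for macrophages) among genes with adjusted p under 0.05, mean CPM of at least 50 and the same direction in every tumour, or no overlap between the groups, and then up to 4 members with the smallest p of each list discussed. Immunoglobulin and T cell receptor genes, genes that mark sex and genes without an approved symbol were left out. For DCIS and IDC a fixed set of 9 genes was reported.

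Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, no filter on low counts, each tumour left out in turn, no block, title number as block, cells without called doublets or with at least 1000 UMIs, purer classes from the clusters, other resolutions and other reference classes. The alternatives chosen after seeing the data were the second call, the UMI minimum of 10763, the barcode lists and leaving out clusters with few UMIs. The tests were tried on simulated data. On counts drawn with known changes in 50 genes of each size, edgeR recovered 2% of 2-fold, 44% of 4-fold and 98% of 16-fold changes in the TNBC design. In the design of ATC against TNBC aneuploid cells it recovered 0%, 10% and 76%. Comparisons of T cell-like, fibroblast-like or endothelial-like cells between the tumour types were not run, since fewer than 3 tumours of a type had enough cells. No gene comparison used the DCIS tumour, a single one, or the 2 IDC tumours, whose libraries are labelled with another chemistry.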

Results

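The data were UMI counts of 36201 cells from 13 tumours, of which the authors called 17739 aneuploid and 18462 diploid. The series asks how copy number profiles and clones of tumour cells can be read from single-cell RNA. Total UMIs and cells per tumour were 27310684 in 1480 cells for DCIS tumour 1. For TNBC tumours 1 to 5 they were 25090243 in 1097, 22242579 in 1034, 14603654 in 532, 56089518 in 3056 and 80078697 in 3225. For ATC tumours 1 to 5 they were 32808176 in 2203, 41403632 in 6226, 33057735 in 3264, 31277114 in 1731 and 80625625 in 6144. For IDC tumours 1 and 2 they were 58168152 in 2831 and 45997967 in 3378.

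Aneuploid cells held more RNA molecules than diploid cells of the same tumour in 13 of 13 tumours. The ratio of median UMIs per cell was 4.11-fold as a geometric mean (1.33 to 9.08). The log2 difference was 2.04 ± 0.843 (SD, n = 13; permutation test over sign flips, two-sided p = 0.000244, the smallest it can give). In TNBC the mean log2 difference was 1.97 ± 1.10 and in ATC 2.30 ± 0.279 (n = 5 each; exact sign-flip p = 0.0625, the smallest possible with 5 tumours). Among cells with at least 10763 UMIs, in the 10 tumours with enough of them, the difference was 0.882. The fewest UMIs per cell differ between libraries, and the low end can differ between the classes of a tumour. In ATC tumour 5 all 2554 aneuploid cells but only 3481 of 3590 diploid cells had at least 1000 UMIs. The ratio was 1.33 to 2.98 in DCIS tumour 1 and TNBC tumours 1 to 3, whose libraries start at 5323 UMIs or more. It was at least 3.84 in every other tumour, so its size goes with the UMI minimum. Depth goes with the class in every comparison of aneuploid and diploid cells.

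**Figure D1:**
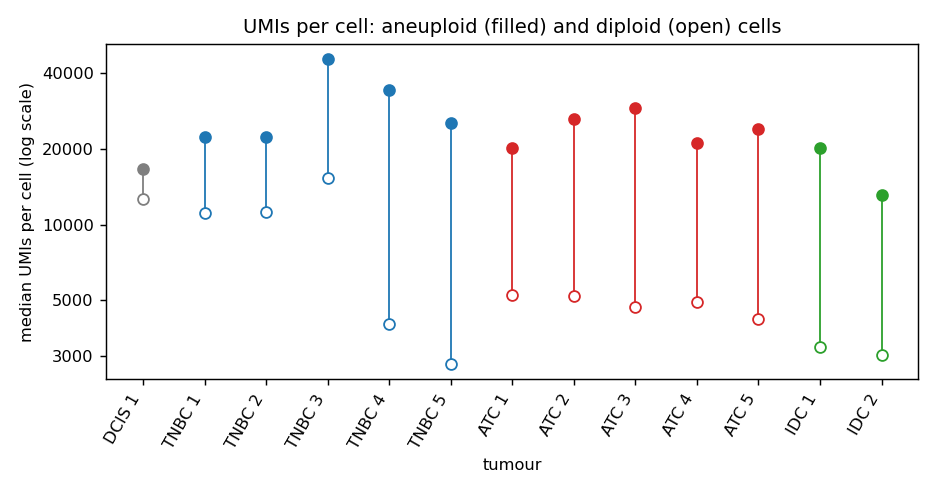
Median UMIs per cell (log axis) of aneuploid (filled points) and diploid (open points) cells in each of the 13 tumours, coloured by tumour type. The filled point lies above the open one in 13 of 13 tumours, from 1.33-fold in DCIS tumour 1 to 9.08-fold in TNBC tumour 5.

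The share of cells called aneuploid ran from 1.98% in ATC tumour 2 to 97.0% in IDC tumour 1 (95% interval 96.3 to 97.6%). It was 37.4% ± 31.3 in ATC and 57.7% ± 21.1 in TNBC (SD, n = 5 each), a difference of -20.3 percentage points. It did not pass an exact two-sided permutation test (p = 0.262, smallest possible 0.00794). Within the barcode lists the difference was -7.72 points (3 against 3 tumours, exact p = 0.7) and -39.1 points (2 against 2, exact p = 0.667). With the common UMI minimum it was -6.74 points. Among the diploid cells, T or NK cell-like cells made up 49.5% ± 33.3 in ATC and 21.9% ± 29.2 in TNBC (SD, n = 5 each; exact p = 0.238). Macrophage or monocyte-like cells made up 20.8% ± 15.3 and 47.7% ± 38.7 (exact p = 0.214), and fibroblast-like cells 8.08% ± 17.3 and 17.24% ± 29.5 (exact p = 0.5). For fibroblast-like cells the direction turned at 0.5 times the cluster resolution (7.91% in ATC and 0.036% in TNBC) and without TNBC tumour 3 (8.08% and 4.22%), and without ATC tumour 1 the difference was -16.91 points in place of -9.16. With the common UMI minimum T or NK cell-like cells were 16.57% and 0.436%, and without ATC tumour 2 their difference was 17.63 points in place of 27.57. Macrophage-like shares were 10.37% and 30.14% at 2 times the resolution, and without TNBC tumour 2 their difference was -14.46 points in place of -26.92. None of 10 classes differed by the exact permutation test (0 at an unadjusted p under 0.05, lowest p 0.127, lowest adjusted p 0.76). Without TNBC tumour 2, plasma cell-like cells were 0.394% and 3.41%, with exact permutation p = 0.00794, the smallest possible, and adjusted p = 0.0794. The lowest exact p of any class was 0.0794 without TNBC tumour 1 or ATC tumour 5 and 0.0556 without TNBC tumour 3, and 0.222, 0.262 and 0.254 without ATC tumours 1, 2 and 3. In single tumours T or NK cell-like cells ranged from 0% of diploid cells in TNBC tumour 3 and 0.446% in ATC tumour 5 to 89.2% in ATC tumour 2. Fibroblast-like cells reached 69.3% in TNBC tumour 3 and 39.1% in ATC tumour 1.

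**Figure D2:**
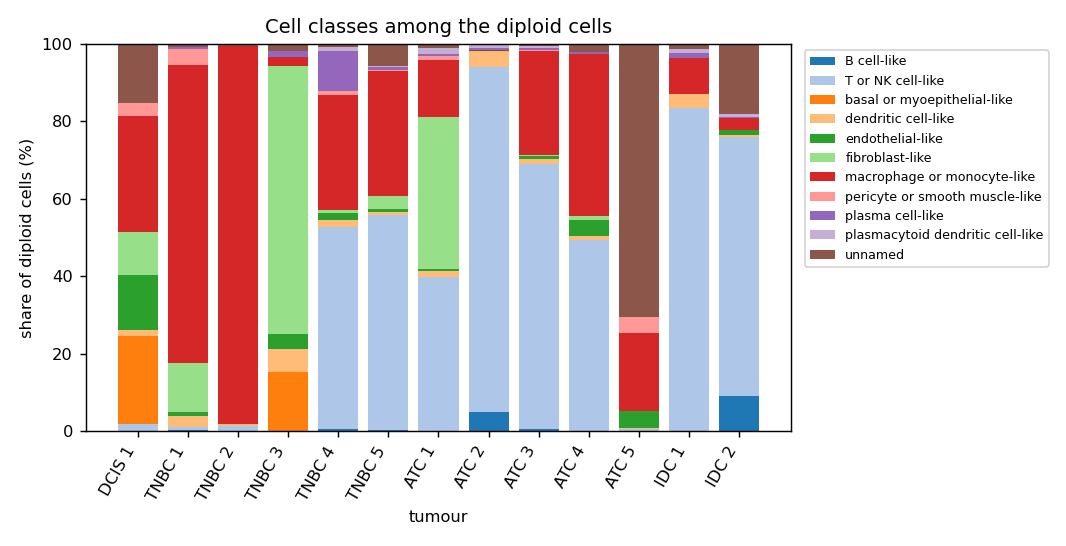
Share of the diploid cells of each tumour (%, stacked bars) in each cell class named from fixed markers, with cells of unnamed clusters in brown. T or NK cell-like cells range from 0% in TNBC tumour 3 to 89.2% in ATC tumour 2.

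In the 5 TNBC tumours, aneuploid cells carried epithelial transcripts at higher levels than diploid cells. The keratin KRT19 stood at 1753 ± 634 CPM in aneuploid and 130 ± 174 CPM in diploid cells (log2 fold change 4.49 ± 0.49, SE; adjusted p = 0.00128; n = 5). RAB25, an epithelial vesicle-trafficking GTPase, stood at 181 ± 60.09 and 10.7 ± 11.1 CPM (4.53 ± 0.50, adjusted p = 0.00134). CD24, a surface sialoglycoprotein, rose by 4.47 ± 0.32 (2528 ± 2315 against 119 ± 109 CPM), the splicing factor ESRP1 by 4.09 ± 0.37, and KRT23 and KRT7 by 4.52 ± 0.35 and 4.31 ± 0.43. Other large rises were those of AARD at 5.01 ± 0.33, the fatty acid-binding protein FABP7 at 4.76 ± 0.63, the phosphatase regulator PPP1R1B at 4.63 ± 0.45, the Wnt inhibitor SFRP1 at 4.52 ± 0.98 and the aldo-keto reductase AKR1B15 at 5.14 ± 0.49. AKR1B15 was high in 1 tumour, at 10.2 as log2(CPM + 1) in its aneuploid cells, against 2.69 in the next. Diploid cells carried the genes of blood and stroma: PTPRC, the pan-leukocyte phosphatase CD45, fell in aneuploid cells by 6.13 ± 0.59 on the log2 scale (3.75 ± 2.08 against 348 ± 279 CPM). HLA-DRA, a chain of the MHC class II molecule, fell by 5.74 ± 0.31 (83.8 ± 49.7 against 4572 ± 2554 CPM). On GRCh38 KRT19 lies on chromosome 17 at 41523617 to 41528308, RAB25 on chromosome 1 at 156061160 to 156070514 and HLA-DRA on chromosome 6 at 32439842 to 32445046.

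By the fixed lists, 17 of 18 measured epithelial genes rose (18 adjusted over the list alone; camera adjusted p = 4.84e-13, adjusted p = 0.428 with an estimated correlation). Of 17 basal keratin and basal-like genes 13 rose (15 over the list alone; adjusted p = 6.51e-08, and adjusted p = 0.432 with an estimated correlation). KRT16 rose by 4.63 ± 0.45 and the cadherin CDH3 by 4.10 ± 0.50. Of 11 milk and secretory breast genes 5 rose (7 over the list alone; adjusted p = 0.000586, and adjusted p = 0.494 with an estimated correlation). The lipocalin LCN2 rose by 4.16 ± 0.47, the protease inhibitor SLPI by 3.73 ± 0.56 and PROM1, which also stands on the basal list, by 4.02 ± 0.65. Of 11 luminal breast genes 4 rose and 1 fell (the same numbers over the list alone; adjusted p = 0.265, with a median log2 fold change of -0.09 and a mean of 0.92). AZGP1 rose by 4.31 ± 0.54 and the transcription factor SPDEF by 3.56 ± 0.91, while ESR1, the oestrogen receptor, fell by 4.28 ± 0.80. All 10 MHC class II genes fell (10 over the list alone; adjusted p = 1.23e-11, and adjusted p = 0.372 with an estimated correlation). The log2 fold change was -6.27 ± 0.33 for HLA-DQA1 and -5.93 ± 0.31 for HLA-DPA1. Of 11 resident and complement macrophage genes 10 fell (10 over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.428 with an estimated correlation). The complement gene C1QC fell by 6.01 ± 0.37, and the mannose receptor MRC1 had -6.26 ± 0.49. Of 25 interferon response genes 14 fell (20 over the list alone; adjusted p = 8.51e-09, and adjusted p = 0.428 with an estimated correlation). Among them were the chemokine CXCL9 (-5.83 ± 0.76), GBP4 (-4.04 ± 0.49) and IRF1 (-2.64 ± 0.47).

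Matrix genes were also on the diploid side in TNBC. Of 18 collagen and matrix genes 12 fell (13 over the list alone; adjusted p = 1.05e-07, and adjusted p = 0.503 with an estimated correlation). Of 20 mesenchymal genes 11 fell (11 over the list alone; adjusted p = 8.37e-07, and adjusted p = 0.372 with an estimated correlation). COL1A2, a chain of type I collagen, fell by 6.15 ± 0.37, and falls were also called for COL3A1 (-5.81 ± 0.40), the fibroblast protease FAP (-5.68 ± 0.38), fibronectin FN1 (-5.11 ± 0.44) and the EMT regulator ZEB1 (-5.24 ± 0.32). Single genes known from leukocytes that fell were the plasma cell chain JCHAIN (-7.11 ± 0.74), SAMSN1 (-6.44 ± 0.51), CD48 (-6.27 ± 0.71) and the interleukin-7 receptor IL7R (-6.19 ± 0.69). Of T cell-like markers 1 of 6 fell (5 over the list alone; adjusted p = 0.00452, and adjusted p = 0.608 with an estimated correlation), of NK cell-like 0 of 5 (0; adjusted p = 0.0687) and of B cell-like 1 of 3 (1; adjusted p = 0.062). Of plasma cell-like markers 3 of 6 fell and 1 rose (the same numbers over the list alone; adjusted p = 0.0651). The further lists of leukocyte genes fell by camera: 12 of 15 NF-kB and cytokine genes fell (12 over the list alone), 8 of 13 monocyte genes (9), and 8 of 16 lipid-associated macrophage genes (10, with 1 higher). So did 4 of 13 cytotoxic T cell genes (10), 6 of 11 T cell exhaustion genes (7), 4 of 7 naive T cell genes (6) and 3 of 12 MHC class I genes (4). Their adjusted p was 7.24e-08 to 0.00178, and adjusted p = 0.308 to 0.676 with an estimated correlation. Of the 12 mitochondrially encoded genes 5 rose (11 over the list alone; adjusted p = 0.000171, and adjusted p = 0.567 with an estimated correlation). Lists without a camera call were thyroid differentiation (2 of 8 called), proliferation (2 of 29), hypoxia (3 of 19), stress and dissociation (3 of 18), nuclear oxidative phosphorylation (1 of 21) and ribosomal protein (0 of 24) genes, with adjusted p of 0.184 to 0.921. Over the list alone 1, 2, 2 and 0 of the proliferation, hypoxia, stress and oxidative phosphorylation genes were called.

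In all, 2358 of 13320 genes were called in TNBC by edgeR, 1043 higher and 1315 lower in aneuploid cells. Of all genes tested 4134 went the same way in 5 of 5 tumours (chance gives 6.25%), among them 2207 of the called ones. Without TNBC tumour 1, 2 or 4 the count was 1196, 1443 or 1124. The call of SFRP1 was lost without each of those and that of SPDEF also without tumour 5. Within the barcode lists 767 (3 tumours) and 803 (2 tumours) genes were called. With macrophage-like cells as the reference COL1A2, COL3A1 and FAP lost their calls, and the direction of COL3A1 turned, as the difference was near 0 (the log2 fold change of COL3A1, aneuploid vs diploid cells, TNBC, was 0.007252).

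In the 5 ATC tumours, aneuploid cells carried far fewer leukocyte transcripts than diploid cells, and MDK and KRT18 were among their rises. MDK, the growth factor midkine, rose by 3.67 ± 0.49 on the log2 scale (1447 ± 2026 against 137 ± 170 CPM; adjusted p = 0.00646; n = 5). The keratin KRT18 rose by 3.72 ± 0.73 (199 ± 96.5 against 18.4 ± 16.1 CPM) and the protease inhibitor SERPINE2 by 3.24 ± 0.53 (199 ± 136 against 22.2 ± 15.95 CPM). LARP6, a collagen mRNA-binding protein, rose by 3.90 ± 0.79, the proteoglycan SPOCK1 by 3.62 ± 0.77, IGFBP6 by 2.63 ± 0.42, BEX3 by 2.51 ± 0.57 and the chondroitin-polymerising factor CHPF by 2.45 ± 0.49. Larger changes were falls: LYZ, lysozyme, fell by 6.95 ± 0.75 (11.99 ± 17.98 against 1135 ± 1365 CPM). The cytotoxic granule gene NKG7 fell by 5.91 ± 0.50 (13.1 ± 12.2 against 842 ± 571 CPM), and HLA-DRB1 fell by 5.75 ± 0.30 (28.4 ± 19.4 against 1500 ± 1093 CPM). B2M, the light chain of MHC class I, fell by 2.01 ± 0.31, from 14781 ± 7714 to 4082 ± 3051 CPM. MDK lies on chromosome 11 at 46380756 to 46383837.

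Of the lists, 11 of 13 cytotoxic T cell genes fell in ATC aneuploid cells (13 over the list alone; adjusted p = 1.25e-12, and adjusted p = 0.428 with an estimated correlation). Examples were the granzyme GZMH (-6.32 ± 0.51) and the T cell co-receptor CD8A (-6.06 ± 0.51). Of 14 T cell exhaustion and regulatory genes 11 fell (13 over the list alone; adjusted p = 3.91e-10, and adjusted p = 0.372 with an estimated correlation), including the checkpoint receptors CTLA4 (-6.07 ± 0.44) and PDCD1 (-6.14 ± 0.64). All 10 MHC class II genes fell (10 over the list alone; adjusted p = 2.48e-13, and adjusted p = 0.321 with an estimated correlation). So did 6 of 12 MHC class I genes (12 over the list alone; adjusted p = 2.48e-07, and adjusted p = 0.428 with an estimated correlation), HLA-F among them (-3.72 ± 0.56). Of 12 resident macrophage genes 8 fell (11 over the list alone; adjusted p = 5.31e-10, and adjusted p = 0.428 with an estimated correlation). Examples were C1QA (-6.26 ± 0.63), VSIG4 (-6.76 ± 0.69) and the haemoglobin scavenger receptor CD163 (-5.87 ± 0.59). The chemokine XCL2 (-7.05 ± 0.52), MNDA (-6.70 ± 0.55), TYROBP, a signalling adaptor of myeloid and NK cells (-6.54 ± 0.59), and the Fc receptor FCGR3A (-6.49 ± 0.58) fell as well. Interferon response genes fell in 3 of 25 cases (11 over the list alone; adjusted p = 9.18e-06, and adjusted p = 0.438 with an estimated correlation). The guanylate-binding protein GBP4 fell by 2.70 ± 0.46. Epithelial genes were called in 1 of 11 cases (2 over the list alone; adjusted p = 0.119). Epithelial-like markers, a shorter list, were higher (1 of 4 called, 3 over the list alone; adjusted p = 0.00538, and adjusted p = 0.478 with an estimated correlation). Collagen genes were called in 0 of 19 (adjusted p = 0.0538), mesenchymal genes in 0 of 22 (2 over the list alone; adjusted p = 0.0508) and thyroid differentiation genes in 0 of 10 (adjusted p = 0.959). Clusters with few UMIs held 2156 of the 3590 diploid cells of ATC tumour 5. COL1A2 stood at 67800 CPM in these clusters and 71600 CPM in the aneuploid cells of that tumour. The lists were not tested without these clusters. The lack of collagen and mesenchymal calls therefore does not show that these genes were alike in aneuploid and diploid cells. Stress and dissociation genes, induced by tissue handling, fell in 2 of 18 cases (6 over the list alone; adjusted p = 3.4e-05, and adjusted p = 0.567 with an estimated correlation).

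For ATC edgeR called 892 of 13729 genes, 180 higher and 712 lower in aneuploid cells. This imbalance depended on tool and reference, with 1539 higher and 1902 lower by DESeq2, and 1685 and 1664 against macrophage-like cells. Of all genes tested 3628 went the same way in 5 of 5 tumours (chance 6.25%), among them 878 of the called ones. Without ATC tumour 2, 3 or 4 the count was 442, 355 or 475. MDK was the one named rise to keep its call with each tumour left out, and the calls of B2M, HLA-F and GBP4 were also lost without each of those 3 tumours. Within the barcode lists 187 genes (3 tumours) and 0 genes (2 tumours; 1230 at an unadjusted p under 0.05) were called by edgeR. With the common UMI minimum 281 were.

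The difference between these contrasts, (ATC aneuploid minus diploid) minus (TNBC aneuploid minus diploid), was large for some mesenchymal genes. FN1, a matrix glycoprotein, had an aneuploid to diploid log2 ratio of 2.39 ± 1.55 in ATC and -4.95 ± 0.84 in TNBC (SD, n = 5 each). The difference was 7.38 ± 0.81 (SE; adjusted p = 0.00318). HTRA1, a secreted serine protease, had 1.33 ± 1.17 and -5.18 ± 0.28 (difference 6.53 ± 0.57, adjusted p = 0.00179). GNG11, a G protein subunit, had 1.17 ± 0.91 and -4.49 ± 0.80 (5.90 ± 0.55) and IGFBP6 2.65 ± 0.93 and -4.47 ± 0.95 (7.36 ± 0.76). The EMT regulators ZEB1 and ZEB2 differed by 4.92 ± 0.69 and 4.58 ± 0.49, the receptor kinase AXL by 7.22 ± 1.16, the integrin ITGA5 by 5.26 ± 0.89 and COL1A2 by 8.75 ± 1.751. The other way went E-cadherin CDH1, with -1.45 ± 0.67 in ATC and 3.72 ± 1.83 in TNBC (difference -5.82 ± 1.09, adjusted p = 0.0346), and KRT23 (-5.79 ± 1.03).

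Of 22 mesenchymal genes 4 differed upwards (13 over the list alone; adjusted p = 1.64e-12, and adjusted p = 0.321 with an estimated correlation). So did 2 of 20 collagen and matrix genes (13 over the list alone; adjusted p = 7.43e-10, and adjusted p = 0.428 with an estimated correlation). Fibroblast-like markers, which include collagens, were called in 1 of 7 cases (5 over the list alone; adjusted p = 0.000573, and adjusted p = 0.481 with an estimated correlation). Of 18 epithelial genes 2 differed downwards (9 over the list alone; adjusted p = 4.57e-08, and adjusted p = 0.428 with an estimated correlation). None of the 12 mitochondrially encoded genes was called (11 lower over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.428 with an estimated correlation). The test called 177 of 15254 genes by edgeR (100 higher, 77 lower). Of all genes tested 773 did not overlap between the types (chance 0.794%), among them 161 of the called ones. The count was 43, 63 and 50 without TNBC tumours 1, 2 and 4, and 330, 77, 38 and 45 without ATC tumours 1, 2, 3 and 4. With barcode list by class as a term it was 106. FN1, HTRA1 and ZEB2 kept their calls in every alternative, and COL1A2 lost its own in 13 of 21.

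Aneuploid cells of ATC and TNBC, compared directly, differed in matrix and epithelial genes, among others. FN1 stood at 2320 ± 1612 CPM in ATC and 14.9 ± 7.995 CPM in TNBC (log2 fold change 7.28 ± 0.73, SE; adjusted p = 0.0005; n = 5 each). The caveolar coat protein CAV1 stood at 691 ± 717 and 4.802 ± 6.11 CPM (7.18 ± 1.17). FAP was higher by 7.58 ± 1.07, IGFBP6 by 8.15 ± 1.43, the growth factor PTN by 7.56 ± 1.72, the coagulation inhibitor TFPI by 7.25 ± 1.08 and COL1A2 by 9.30 ± 2.32. RAB25 was at 0.0489 CPM in ATC and 187 ± 62.9 CPM in TNBC (-11.33 ± 0.86, adjusted p = 0.000197) and ESRP1 at 0.111 and 72.8 ± 16.5 CPM (-8.84 ± 0.98). CALML5, a calmodulin-like protein of differentiating epidermis, had 0 of 129865855 UMIs over the ATC tumours and a mean of 1887 CPM in TNBC. With 3 counts over the group as the floor, ATC was at least 81670-fold below that mean. The lowest TNBC tumour stood at only 2.92 as log2(CPM + 1), against 10.7 in the next, so the bound does not hold for each tumour. On GRCh38 FN1 lies on chromosome 2 at 215360440 to 215436172, ESRP1 on chromosome 8 at 94641074 to 94707466 and CDH1 on chromosome 16 at 68737225 to 68835548.

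Of 21 mesenchymal genes 10 were higher in ATC (13 over the list alone; adjusted p = 1.88e-11, and adjusted p = 0.234 with an estimated correlation). ZEB1 stood at 44.4 ± 20.7 against 0.720 ± 0.367 CPM (5.95 ± 0.60), and ZEB2 and ITGA5 were higher by 5.60 ± 0.76 and 5.60 ± 0.69. Of 19 collagen and matrix genes 10 were higher (16 over the list alone; adjusted p = 2.85e-11, and adjusted p = 0.321 with an estimated correlation). So were 2 of 7 fibroblast-like markers (5 over the list alone; adjusted p = 0.000145, and adjusted p = 0.428 with an estimated correlation). Of 18 epithelial genes 10 were lower (14 over the list alone; adjusted p = 7.94e-17, and adjusted p = 0.27 with an estimated correlation). CDH1 stood at 0.342 against 129 ± 105 CPM (-9.16 ± 1.34), and the tricellular junction gene LSR was lower too (-4.04 ± 0.60). Of 12 basal genes 4 were lower (7 over the list alone; adjusted p = 0.000168, and adjusted p = 0.428 with an estimated correlation), such as KRT15 (-7.47 ± 1.30) and TRIM29 (-5.09 ± 1.36). Of 10 luminal genes 3 were lower (5 over the list alone; adjusted p = 0.00253, and adjusted p = 0.473 with an estimated correlation). They were AZGP1 (-12.89 ± 2.097), SPDEF (-8.79 ± 1.53) and the receptor kinase ERBB2 (13.6 ± 5.34 against 37.6 ± 8.09 CPM, -1.46 ± 0.35). Milk and secretory breast genes were also lower (2 of 10 called, 4 over the list alone; adjusted p = 0.000322, and adjusted p = 0.435 with an estimated correlation). NF-kB and cytokine genes were higher (2 of 16, 8 over the list alone; adjusted p = 0.00354, and adjusted p = 0.594 with an estimated correlation), as were cytotoxic T cell genes as a list (0 of 13 called; adjusted p = 0.0301, and adjusted p = 0.759 with an estimated correlation). T or NK cell-like cells made up 49.5% of the diploid cells in ATC and 21.9% in TNBC. Their free RNA or missed doublets as a source of the cytotoxic genes were not tested. Of 9 thyroid differentiation genes 1 was higher in ATC (1 over the list alone; adjusted p = 0.72). This was the transcription factor GLIS3, at 17.19 ± 10.4 against 0.797 ± 0.642 CPM (4.39 ± 0.73). Of 29 proliferation genes 2 were lower (2 over the list alone; adjusted p = 0.0401, and adjusted p = 0.786 with an estimated correlation). These were the cyclin kinase subunit CKS1B, at 65.6 ± 20.02 against 281 ± 152 CPM, and the replication licensing factor MCM4 (-1.97 ± 0.53). The 12 mitochondrially encoded genes were lower as a list with 0 called (adjusted p = 0.00139, and adjusted p = 0.578 with an estimated correlation).

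**Figure D3:**
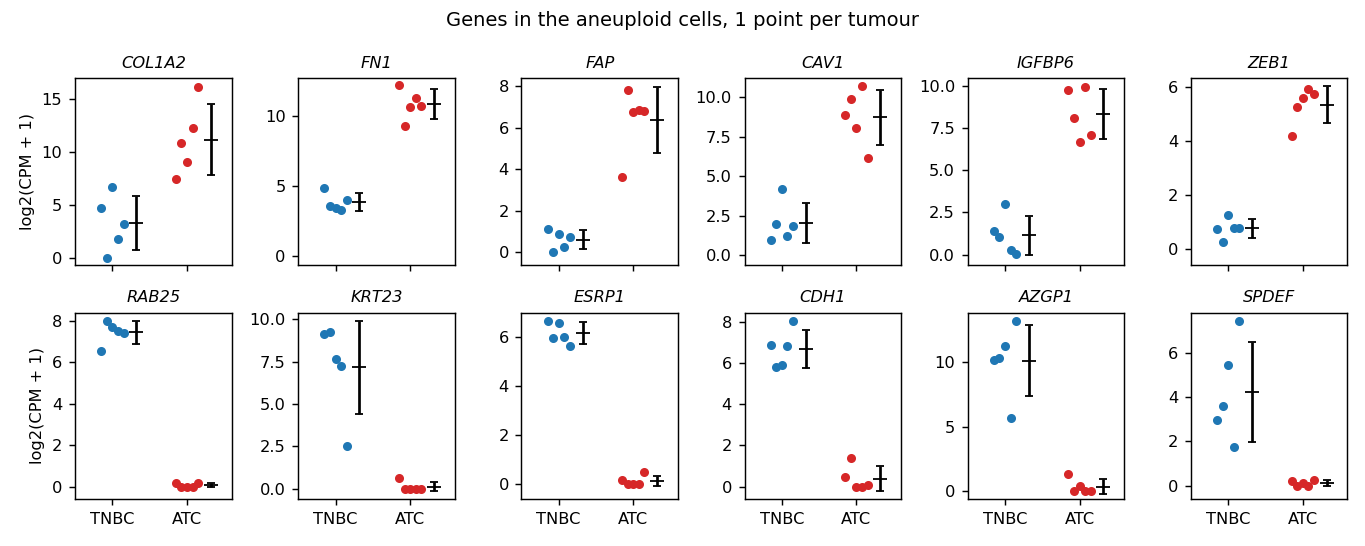
Levels of 12 genes in aneuploid cells as log2(CPM + 1) without TMM scaling, with 1 point per TNBC (blue) or ATC (red) tumour and the mean and SD of 5 tumours in black. The matrix and mesenchymal genes of the upper panels are higher in ATC, such as FN1, and the epithelial genes of the lower panels are near 0 there.

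Here edgeR called 1000 of 13842 genes, 507 higher and 493 lower in ATC. Of all genes tested 1209 did not overlap between the types (chance 0.794%), among them 771 of the called ones. Without TNBC tumour 2 or ATC tumours 3 or 4 it called 644, 638 or 603. Within the barcode lists 927 genes (3 against 3 tumours) and 0 genes (2 against 2; 1608 at an unadjusted p under 0.05) were called by edgeR, and 990 with the list as a term. The call of COL1A2 was lost in 10 of 21 alternatives. Organ, sample type and tumour type are confounded in this comparison.

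Macrophage or monocyte-like cells of the tumour types differed in few genes. CTSK, the collagen-degrading cathepsin K of osteoclasts, stood at 7.46 ± 4.21 CPM in ATC and 314 ± 287 CPM in TNBC (log2 fold change -5.43 ± 0.72, SE; adjusted p = 0.0105; 5 ATC and 4 TNBC tumours). CKB, brain-type creatine kinase, stood at 5.49 ± 4.54 and 191 ± 58.0 CPM (-4.81 ± 0.49, adjusted p = 0.001). FPR1, the formyl peptide receptor of phagocytes, stood at 141 ± 75.2 and 26.3 ± 8.59 CPM (2.44 ± 0.44, adjusted p = 0.0481). SLC9B2 (-4.73 ± 0.58) and SIGLEC15 (-3.59 ± 0.62), both known from osteoclasts, were also lower in ATC and were chosen after their values were seen. Epithelial genes went with the TNBC side in these cells too. EPCAM was at 0.149 ± 0.218 and 23.4 ± 12.4 CPM (-6.01 ± 0.63), CLDN3 at 0.0531 and 23.5 ± 12.3 CPM (-7.73 ± 0.82), and ELF3 was lower in ATC (-4.82 ± 0.62). CTSK lies on chromosome 1 at 150796208 to 150808323 and CKB on chromosome 14 at 103519659 to 103523111.

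Of 14 epithelial genes 3 were lower in ATC macrophages (12 over the list alone; adjusted p = 3.43e-23, and adjusted p = 0.196 with an estimated correlation). Monocyte and inflammatory genes were higher as a list (0 of 13 called, 7 over the list alone; adjusted p = 4.18e-08, and adjusted p = 0.321 with an estimated correlation). Stress and dissociation genes were also higher as a list (0 of 18 called, 0 over the list alone), with adjusted p = 4.88e-06, and adjusted p = 0.473 with an estimated correlation. Resident and complement macrophage genes were higher as a list at adjusted p = 3.42e-05 (0 of 12 called, 2 over the list alone), and adjusted p = 0.428 with an estimated correlation. Other lists higher in ATC by camera were hypoxia (adjusted p = 0.000731), NF-kB and cytokine (0.0105) and collagen and matrix genes (0.0261), and the neutrophil-like (0.000617), fibroblast-like (0.0153) and macrophage or monocyte-like markers (0.0201). None of these had a called gene, and with an estimated correlation the lowest adjusted p among them was 0.321. Lipid-associated and SPP1 macrophage genes did not pass (0 of 16, 1 lower over the list alone; adjusted p = 0.271), nor did MHC class II genes (0 of 10; adjusted p = 0.494). In all 18 of 10410 genes were called by edgeR, 7 higher and 11 lower in ATC, while DESeq2 called 76 higher and 29 lower. Of all genes tested 292 did not overlap between the types (chance 1.59%), among them the 18. Without TNBC tumours 1 or 2 the count was 7 or 10 and without ATC tumours 2 or 3 it was 10 or 11. With the barcode list as a term it was 46 (25 higher, 21 lower), and within the lists 111 (2 TNBC against 3 ATC) and 6 (2 against 2). At 2 times the cluster resolution 1 gene and with the common UMI minimum 3 genes were called, none of the 8 named here. The call of FPR1 was lost in 14 of 20 alternatives.

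**Figure D4:**
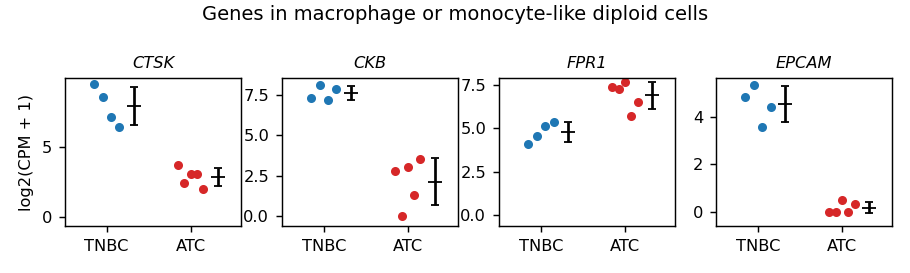
Levels of CTSK, CKB, FPR1 and EPCAM in macrophage or monocyte-like diploid cells as log2(CPM + 1) without TMM scaling, with 1 point per tumour (4 TNBC in blue, 5 ATC in red) and the mean and SD in black. The groups do not overlap for any of the 4 genes, and FPR1 is the one that is higher in ATC.

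Along the genome, expression in TNBC aneuploid cells relative to diploid cells was higher over 8q (log2 0.90 ± 0.167, SE; limma adjusted p = 9.67e-06; 5 of 5 tumours), 1q (0.69, adjusted p = 0.00117; 5 of 5) and 6p (0.56, adjusted p = 0.0145; 4 of 5) and lower over 15q (-0.53, adjusted p = 0.0198; 4 of 5 lower). In ATC it was higher over 5p (0.49 ± 0.12, adjusted p = 0.00531; 5 of 5), 7p (0.42 ± 0.11, adjusted p = 0.00531; 5 of 5) and 20p (0.42 ± 0.12, adjusted p = 0.0164; 4 of 5). It was lower over 13q (-0.52 ± 0.12, adjusted p = 0.00531; 5 of 5). With the mean over genes in place of the median, 5p, 7p and 20p in ATC (adjusted p = 0.0546, 0.0669 and 0.374) and 1q and 6p in TNBC (0.0867 each) were not called. With mean CPM of at least 50 the 1 ATC arm called was 13q. With macrophage-like cells as the reference 1 ATC arm was called, a rise, so 13q lost its call. In ATC tumour 5, 2156 of the 3590 diploid cells came from clusters with few UMIs. Their arm profile had a correlation of 0.92 with that of its aneuploid cells. The arms were not scored against all diploid cells without these clusters. ATC lay below TNBC over 8q (-0.93 ± 0.20, adjusted p = 0.000411), 1q (-0.92 ± 0.19, adjusted p = 0.000339), 6p (-0.73 ± 0.21, adjusted p = 0.0104) and 10p (-0.59 ± 0.20, adjusted p = 0.0375). These are expression values, and the classes were called from such profiles, so they measure how the called cells look rather than testing the call. As background, macrophage-like against T or NK cell-like diploid cells of 4 ATC tumours also gave 9 arms past the threshold. Over the 6 tumours with both classes that background had an SD over arms of 0.124, against 0.359 for the aneuploid cells of the same tumours. Without TNBC tumours 1, 2 or 5 the count of 4 TNBC arms became 2, 2 or 7. The 4 ATC arms became 0 without ATC tumour 3 (limma, 8 at an unadjusted p under 0.05) or 4 (5), and 6 without tumour 2. Between the types the arms called without ATC tumour 3 or TNBC tumour 1 were 1q and 8q, and 6 were called without TNBC tumour 5.

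**Figure D5:**
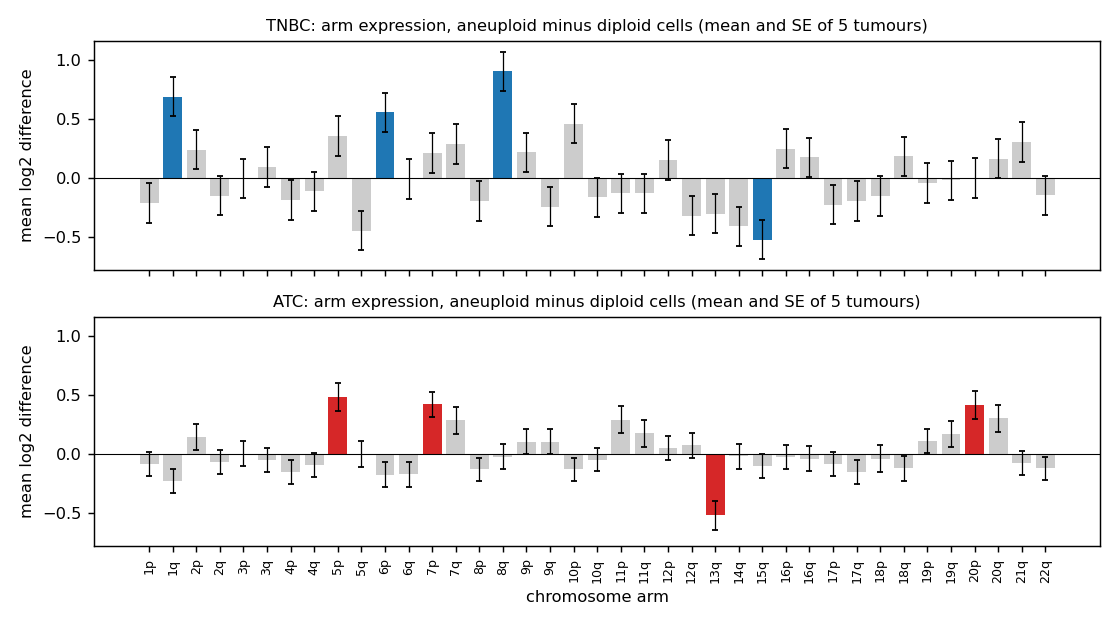
Mean log2 difference in expression between aneuploid and diploid cells over each chromosome arm, with the SE of the limma fit to 5 tumours, for TNBC (upper panel) and ATC (lower panel). Coloured bars are the 4 arms of each type with adjusted p under 0.05 and grey bars the others.

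Aneuploid cells of 9 of 13 tumours divided into a pair of groups whose profiles along the genome were repeated by genes not used for the split: 1 of 1 DCIS, 4 of 5 TNBC, 2 of 5 ATC and 2 of 2 IDC tumours. The correlation between the gene sets had a median of 0.413 (0.038 to 0.81). Macrophage-like cells passed the same test in 3 of 7 tumours, with a correlation of up to 0.436, and 5 of the 13 aneuploid sets lay above that background. With bins of 50 genes, 15 genes or k-means the number was 12, 10 and 10, of which ATC tumours were 5, 2 and 3.

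The DCIS and IDC tumours, which were not tested against TNBC, held the oestrogen receptor gene ESR1, which TNBC aneuploid cells nearly lacked. The IDC libraries are labelled 5' and the others 3', so for IDC chemistry and tumour type cannot be told apart. ESR1 stood at 306 CPM in aneuploid cells of DCIS tumour 1 (95% interval 298 to 314) and at 190 (187 to 194) and 257 (252 to 262) CPM in IDC tumours 1 and 2, against 0.496 ± 0.443 CPM in TNBC (SD, n = 5). GATA3, a luminal transcription factor, stood at 698, 1675 and 1052 CPM against 42.5 ± 42.7. PGR, the progesterone receptor, stood at 31.6, 0.487 and 5.27 CPM against 0.102 ± 0.221. KRT8 was at 1584, 5447 and 620 CPM against 538 ± 266, EPCAM at 265, 213 and 377 CPM against 782 ± 364 and ERBB2 at 29.3, 69.1 and 13.1 CPM against 37.0 ± 6.999. The basal keratin KRT5 was at 0.552 CPM in DCIS tumour 1 and at 0 in the IDC tumours, which allows up to 0.0522 and 0.0681 CPM, against 12.5 ± 18.3. KRT14 was at 2.31, 0.870 and 0.114 CPM against 224 ± 387. The proliferation marker MKI67 was at 0.953, 28.0 and 12.5 CPM against 51.1 ± 35.6.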

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

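The tests of T or NK cell-like shares, of CTSK alone against aneuploid cells and of the arm profile of fibroblast-like cells were chosen after their results had been seen, and the others here before. The aneuploid minus diploid change differed between ATC and TNBC, by the test of the difference itself, in 18 named genes. The difference (log2, ATC minus TNBC) was 8.75 for COL1A2, 7.38 for FN1, 7.36 for IGFBP6, 7.22 for AXL, 7.09 for the secretory chaperone SCG5, 6.53 for HTRA1, 6.05 for the transglutaminase TGM2, 5.90 for GNG11, 5.26 for ITGA5, 4.92 for ZEB1 and 4.58 for ZEB2. It was -5.82 for CDH1, -5.79 for KRT23, -2.04 for ENSA, -1.88 for PCMTD1, -1.65 for ATF6B, -1.64 for SMARCC1 and -1.60 for ABI1.

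A tumour far from the other 4 of its group was found in 27 of 208 sets of values tested (13%). Chance gives about 1 in 20 for independent, normally distributed values. These sets reuse the same tumours over related genes and some lie near 0, so the 13% does not show an excess. The gap to the nearest tumour is given as a share of the group's range. In TNBC aneuploid cells, AKR1B15 was high in 1 tumour (log2(CPM + 1) 10.2, next 2.69, gap 0.751) and CXCL9 as well (2.35, next 0.564, gap 0.76). SFRP1 was low in 1 tumour (0.175, next 8.81, gap 0.795), as were KRT16 (0.574, next 4.8, gap 0.827) and CALML5 (2.92, next 10.7, gap 0.889). In TNBC diploid cells the gap was 0.963 for AKR1B15, 0.822 for ESRP1 and 0.724 for ESR1 at the high end, and 0.837 for SAMSN1, 0.897 for HLA-DQA1, 0.76 for HLA-DQA2 and 0.751 for HLA-DPA1 at the low end. In ATC aneuploid cells leukocyte genes were high in 1 tumour, with gaps of 0.799 for XCL2, 0.798 for VSIG4, 0.766 for FCGR3A and 0.74 for C1QA, while HLA-DRB1 was low (0.717), as were FAP (0.751) and ITGA5 (0.778). SMIM22, KRT23 and PPP1R1B, near 0 in ATC, had gaps of 0.801, 1.0 and 0.951. In ATC diploid cells HLA-DRB1 (0.729), B2M (0.862), GZMH (0.821) and NKG7 (0.787) were low in 1 tumour, and in ATC macrophage-like cells CLDN3 was above 0 in 1 tumour (gap 1.0).

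T or NK cell-like cells were at most 1.21% of the diploid cells of TNBC tumours 1 to 3, whose libraries start at 7396 to 10763 UMIs, and had a median of 52.1% in the 7 other TNBC and ATC libraries, which start at 509 to 848. Tumour type as the cause cannot be told apart: TNBC tumours 4 and 5, at 52.1% and 55.5%, lie inside the range of the ATC tumours (0.446 to 89.2%), but so do TNBC tumours 1 and 2. A filter on UMIs may be the cause: over cells with at least 10763 UMIs the median of the 7 libraries fell to 4.84%, against at most 0.602% in the 3. That value decides nothing, since as few as 3 diploid cells of a library were left and the 7 ranged from 0% to 56.9%, so a filter and a true lack of T cells in these tumours cannot be told apart.

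Clusters with few UMIs held 2156 of the 3590 diploid cells of ATC tumour 5. Their median was 3906.5 UMIs, against 4737.5 in its other diploid cells and 23992.5 in its aneuploid cells. Free RNA in droplets, drawn from all cells of the library alike, is argued against by macrophage markers. These stood at a median log2 ratio of -3.05 to the other cells of the library (upper quartile -2.68). Free RNA mainly from aneuploid cells would lack these markers too and would carry the arm profile given below. It cannot be told apart from tumour cells with few UMIs. The planned marker test came out as predicted for fibroblasts (median log2 ratio of -0.623 to fibroblast-like cells). In a test chosen later, the arm profile of fibroblast-like cells was set against that of the aneuploid cells of this tumour. It had r = 0.12 in the 1 other ATC tumour with enough of them and -0.442 for 761 such cells pooled over tumours. These tests disagree. DCN, an abundant fibroblast proteoglycan, stood at 167 CPM in the clusters and 3940 CPM in fibroblast-like cells, and LUM, COL1A1 and FBLN1 were lower too. COL3A1 (6790 and 6540 CPM), PDGFRA (242 and 203) and COL1A2 were not. The smaller cluster (272 cells in all) had DLK1, IGF2, ASPN and OGN among its leading genes, and the clusters were tested together only. Tumour cells with few UMIs, as a hypothesis, are consistent with a correlation over 39 arms of 0.92 with the tumour's own aneuploid cells, against at most 0.297 with those of any other ATC tumour (0.0675 with the macrophage-like cells of this tumour as their reference), and with COL1A2 at 67800 CPM in the clusters, 71600 in aneuploid and 5580 in fibroblast-like cells. The nuclear RNA MALAT1 stood at 59900 CPM in the clusters and 17000 in aneuploid cells, and without the clusters the ATC comparison called 1081 genes.

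Among macrophage-like cells, free RNA of aneuploid cells may account for the epithelial genes of TNBC: in TNBC tumours 4 and 5 these stood at a median log2 ratio of -0.975 and -0.642 to T or NK cell-like cells, within the range set for RNA that enters every class alike. For CTSK that source is argued against, since its CPM was at least 8.33 times that of the aneuploid cells in each of 4 TNBC tumours. For CTSK with CKB it cannot be told apart, since CKB reached 0.621 times the aneuploid level in TNBC tumour 1 and more than that level in the other 3. For CTSK, free RNA of fibroblast-like cells is argued against by a CTSK to COL1A2 ratio at least 58.2 times that of those cells. That reference pooled 318 fibroblast-like cells of TNBC, 244 of them from TNBC tumour 3, which was not among the 4 tumours. CKB was not tested against fibroblast-like cells. A different mix of macrophage clusters stays open: of the 2 clusters with at least 20 cells in 1 ATC and 2 TNBC tumours, 1 had no CTSK or CKB among 70470 ATC UMIs, which makes them at least 23.1-fold and 26.3-fold higher in TNBC (floor of 3 counts over the group), and the other had ratios of 2.01 and 1.39, with only 1 ATC tumour behind each, and tumour type is confounded with organ and sample type.

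Splits of the same samples, with the real grouping counted among them, tested whether chance could give as many calls. Chance is unlikely for the difference between the contrasts (177, highest other 11, as large in 1 of 100 splits). The same holds for ATC against TNBC aneuploid cells (1000, highest other 75, 1 of 100). Aneuploid and diploid cells come from the same tumours, and the 16 splits that part every pair are too few for a share under 0.05: in TNBC 2358 genes were called (highest other 6) and in ATC 892 (highest other 0). Over 100 splits that mostly break the pairs 1 was as large in TNBC and 2 in ATC. In ATC a split that does not part every pair gave 1149, and the cause of that was not tested. Macrophage-like cells gave 18 genes, reached by 2 of 100 splits, and the split with 155 followed the barcode lists in 9 of 9 tumours; with the list as a term the count was 46, and within the lists 111 and 6. For arms between the tumour types 4 calls were reached by 2 of 100 splits (highest other 5). Arms within TNBC (4 calls, highest other 5, as large in 2 of 16) and within ATC (4, highest other 0, 1 of 16) have too few splits for a share under 0.05.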

How the results depend on the processing

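The UMI minimum of 10763, the second deposited call, macrophage-like cells as the reference for genes, the barcode lists and the removal of clusters with few UMIs were chosen after the data had been seen, and the other alternatives before. Of the 657 gene results in TNBC aneuploid against diploid cells, 621 kept direction and call, 35 lost the call and 1 reversed: the log2 fold change of COL3A1, aneuploid vs diploid cells, TNBC, was 0.007252 with macrophage-like cells as the reference. In ATC 402 of 520 kept it and 118 lost it, and for the difference between the contrasts 259 of 378 and 119. For ATC against TNBC aneuploid cells the numbers were 582 of 680 and 98, and for macrophage-like cells 113 of 159 and 46. For arms and cell classes together they were 98 of 136 and 38. The named genes called in every setting were 20 of 39 in TNBC, 3 of 18 for the difference and none in the other 3 comparisons. For ATC and for ATC against TNBC aneuploid cells the fit within the second barcode list called no gene at all, so none could be, and the difference had no such fit.

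Counts of called genes that moved by over 1.5 times are given in the order TNBC, ATC, difference, ATC against TNBC aneuploid cells, macrophage-like cells. With DESeq2 they were 4257, 3441, 1842, 2310 and 105. With 1 tumour left out they ran from 1124 to 2676, 355 to 989, 38 to 330, 603 to 1253 and 7 to 27. In TNBC they were 1196, 1443 and 1124 without tumours 1, 2 and 4. In ATC they were 442, 355 and 475 without tumours 2, 3 and 4. For the difference they were 43, 63 and 50 without TNBC tumours 1, 2 and 4 and 330, 77, 38 and 45 without ATC tumours 1 to 4. For aneuploid cells they were 644, 638 and 603 without TNBC tumour 2 and ATC tumours 3 and 4. For macrophage-like cells they were 7 and 10 without TNBC tumours 1 and 2, and 10 and 11 without ATC tumours 2 and 3. Within the barcode lists, with fewer tumours, they were 767 and 803 in TNBC, 187 and 0 in ATC, 0 in the second list for aneuploid cells (1608 by edgeR at an unadjusted p under 0.05) and 111 and 6 in macrophage-like cells. With the UMI minimum the ATC count was 281, the difference 24 and macrophage-like cells 3. With macrophage-like cells as the reference ATC gave 3349 (1685 higher, 1664 lower) and the difference 309. Without a tumour block ATC gave 587 and the difference 79. The second call gave 116 for the difference, and barcode list as a term 106, or 46 in macrophage-like cells. Title number as a block gave 344 in aneuploid and 10 in macrophage-like cells. For macrophage-like cells no filter on low counts gave 31, and 0.5 and 2 times the resolution 5 and 1. For the results in this paragraph other than fits with fewer tumours the cause was not tested.

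The 4 ATC arms (3 higher, 1 lower) became 1 lower with mean CPM of at least 50, 1 higher with macrophage-like cells as the reference, and 4 lower with the mean over genes, where TNBC had 1 higher and 4 lower in place of 3 and 1. With 1 tumour left out ATC had 0 to 6 arms (0 by limma without tumours 3 and 4, with 8 and 5 at an unadjusted p under 0.05), TNBC 2 to 7 (2 without tumours 1 and 2, 7 without tumour 5) and the difference 2 to 6 (2 without ATC tumour 3 or TNBC tumour 1). With 1 tumour left out the share of aneuploid cells differed by -30.97 to -11.43 points and UMIs per cell by 1.94 to 2.18. With the UMI minimum these were -6.74 points and 0.882, and within the barcode lists the share differed by -7.72 and -39.1 points. Of 114 tests of the gene lists camera called 54 with the preset correlation, and 79 of 200 with the cell type markers included. With an estimated correlation it called 0 of the 200, and the lowest adjusted p was 0.196. The T cell and fibroblast references for TNBC arms were not run, since too few tumours had those cells. Small changes can be missed: on simulated counts edgeR recovered 2% of 2-fold changes within TNBC. Between tumour types it recovered 0% in aneuploid cells and 10% in macrophage-like cells.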

Other observations

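The osteoclast gene test was chosen after the macrophage genes had been seen. Plasma cell-like cells were called aneuploid in 179 of 436 cells (41.1%), 153 of them among the 346 such cells of TNBC tumour 4. The cells called aneuploid had a median of 2085 UMIs and the 257 called diploid 20403. The share depended on the clustering, with 3.86% of 233 plasma cell-like cells called aneuploid at 0.5 times the resolution and 3.83% of 235 at 2 times. Diploid cells of DCIS tumour 1 were mixed, with 29.96% macrophage-like, 22.7% basal or myoepithelial-like, 14.1% endothelial-like and 11.2% fibroblast-like cells. KRT5 and KRT14 stood at 43.3 and 249.5 CPM in those diploid cells against 0.552 and 2.31 CPM in the aneuploid cells of the same tumour. In IDC tumour 1, 71 of 85 diploid cells were T or NK cell-like (83.5%, 95% interval 73.9 to 90.7%), and in IDC tumour 2 66.7% (62.1 to 71.0%), with 9.21% B cell-like.

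CTSK and CKB are known from osteoclasts, the bone-resorbing relatives of macrophages. A hypothesis is that macrophage-like cells of these TNBC tumours were in an osteoclast-related state, in which case other osteoclast genes would be lower in ATC too. Of 17 genes of an osteoclast list that were measured, 4 were called (CTSK, CKB, SLC9B2 and SIGLEC15), and of the 13 others 10 were lower in ATC, with a median log2 fold change of -0.225 (camera two-sided p = 0.000413, and p = 0.00728 with an estimated correlation). Among these, ACP5, the tartrate-resistant phosphatase, stood at 182 ± 133 CPM in ATC and 856 ± 526 CPM in TNBC (-2.21 ± 0.57, edgeR adjusted p = 0.251) and the gelatinase MMP9 at 197 ± 178 and 1174 ± 861 CPM (-2.58 ± 0.94, edgeR adjusted p = 0.484). DCSTAMP (log2 fold change 0.298), ATP6V0D2 (0.273) and CLCN7 (0.083) were not lower. OSTM1 (-0.026), CA2 (-0.169), JDP2 (-0.172) and SRC (-0.225) were near 0, so the fall was not shared by the whole list. The test is consistent with such a state, but list and test were chosen from these data, and CTSK in DCIS tumour 1 was at 97.0 CPM (189 UMIs in macrophage-like cells). A different mix of macrophage clusters is open as well: ATC macrophage-like cells were 53.8% and 39.0% from 2 clusters, and those of TNBC 45.8% and 35.6% from 2 others. Single tumours carried the second cluster of each, as ATC tumour 5 gave 83.9% and TNBC tumour 4 gave 87.5% of its cells.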
